A study of Mus musculus with 26 samples.

How the data were processed

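RNA sequencing measured poly(A)-selected transcripts of the spleen of female BALB/c mice aged 8 weeks. Per the labels, 26 libraries fall into 3 treatments. The mice received saline, ovalbumin (OVA, an egg-white protein used as an allergen in mice) at 0.05 mg per day, or OVA with a mimic of the microRNA miR-676-3p. Injections into the peritoneum were given on days 1, 3 and 5, and the mimic went into the tail vein at 7 mg per kg on day 3. The labels give 20 mice per group. They do not say whether each library is a separate mouse, so p-values are read as the spread between these libraries at most. Those from random sets of genes, used for the microRNA sites, measure the spread between genes only. Each library also carries a code, CT for saline, OS or ON for OVA, and MM or MN for OVA with the mimic. The labels do not define the codes, which were kept as the labels give them.

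The deposited table holds FPKM (fragments scaled by gene length and by library size) for 56392 genes, with a gene length for each. The authors' processing notes name CASAVA, HISAT2 2.0.5, StringTie 1.3.3b, featureCounts 1.5.0-p3, DESeq2 1.20.0 and edgeR 3.24.3, with no role for any of them. The genome build is not given in the sources used here. Of 52083 gene IDs shared with a GRCm38 annotation, 2.80% have its coordinates, so gene positions below are those of the deposited table on a build it does not name. In all 26 libraries 100% of FPKM values, multiplied by gene length, were whole multiples of a single step (tolerance 0.05), which gave the reads behind each value. Recovered reads ranged from 14224832 in MM 2 to 18113989 in ON 4. The effective library size in the deposited values ranged from 0.712 of the recovered reads in ON 2 to 1.12 in ON 1. A single read on 1 kilobase corresponds to an FPKM of 0.0520 to 0.0899, which sets the precision at low values. The reads carry no stated molecular identifiers, so this precision covers counting error only.

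Genes with an FPKM of at least 1 in at least 5 libraries were tested, which left 15672 genes, 11969 of them protein-coding. Values were log2(FPKM + 1). limma 3.58.1 in R 4.3.3 fitted 1 mean for each of the 5 codes over all 26 libraries, with a variance trend, and p-values were adjusted by Benjamini-Hochberg within each of 13 comparisons at a threshold of 0.05. OVA is the average of the means of OS and ON, and OVA with mimic that of MM and MN. Log2 differences are given with their standard error, and FPKM as mean ± SD. FPKM are not counts, so no count model was the first choice, and limma voom on the recovered reads was added as a further tool.

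Named genes were the 10 with the largest rise and the 10 with the largest fall among those past the threshold with a mean FPKM of at least 1 in the higher group, for the 3 treatment comparisons, OS against ON and MM against MN. Predicted and unnamed genes, clone names, pseudogenes and antigen receptor segments were left out of naming but not of counts. Where no gene passed, the genes with the 5 smallest p-values are given, predicted genes and pseudogenes included. For each gene list, up to 4 passing members with the smallest p, and up to 2 that did not pass with the highest FPKM, could also be named. Of the genes these rules name, 2 are not reported here. There were 41 lists, 35 by symbol and 6 by name pattern, and 601 of 602 symbols matched the table. Each list was tested with camera at a preset correlation of 0.01 and again with an estimated correlation, and its members were also counted with p adjusted over the list alone. These rules, the lists and the comparisons were chosen before the data were examined.

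A fit to simulated data with known changes, with the size of these libraries and their spread per gene, was tested first. The simulated genes varied independently of each other and no library was set apart. The rates below therefore do not cover variation shared between genes or outlying libraries such as CT 4 and ON 2. In OVA against saline it recovered 34.3%, 64.2% and 95.5% of genes changed 1.5, 2 and 4 times, with 8 false calls. In OVA with mimic against OVA these were 49.3%, 83.6% and 95.5%, with 5 false calls.

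For the opposite movement of the OVA and mimic effects, the OVA libraries were divided by odd and even replicate number so that the 2 effects shared no library, and r across genes was compared with 100 relabellings of the OVA and mimic libraries. For the microRNA, the mature sequence CCGTCCTGAGGTTGTTGAGCT was typed from memory, not taken from a database, and was then found at bases 55 to 75 of the annotated 89-base precursor, on GRCm38 chromosome X from 100381097 to 100381185 on the + strand. The start of the mature form, which sets its seed, was not checked against another source. Matches to its bases 2 to 8 (CAGGACG) were counted in 3′ UTRs taken from a transcript sequence set and its annotation, and a genome sequence was not used here. Site genes were compared with genes without a site, and with 10000 random sets of genes without a site, matched on expression and 3′ UTR length. The labels do not give the sequence of the mimic, which was taken to be the mature miR-676-3p.

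Alternatives fixed beforehand were a pseudocount of 0.1, no filter on low values, an FPKM of at least 5, median-ratio scaling, a fit to only the libraries compared, replicate numbers as a block, a single mean per treatment, library weights, an 8-base site, and leaving out each library in turn. Alternatives chosen after seeing the data were voom, scaling to total reads, leaving out the 3 libraries with over 1% of reads on pancreatic genes, removal of a trend with gene length, and the gene lists without each library in turn. Replicate numbers did not pair the libraries. Of 50 pairs with the same number, 9 had a correlation over 0.1 after group means were removed (median -0.0437). Of 325 pairs of libraries none were duplicates, the nearest being ON 4 and ON 5 with a chi-square per degree of freedom of 7.40. Calculations outside R used Python 3.11.15 with numpy 2.4.6, and plots used matplotlib 3.10.9.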

Results

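The 26 libraries comprised 5 from mice given saline, 11 from mice given OVA (6 coded OS and 5 coded ON) and 10 from mice given OVA with the miR-676-3p mimic (5 coded MM and 5 coded MN). Recovered reads ranged from 14224832 to 18113989 per library. Genes of the exocrine and endocrine pancreas, an organ that adjoins the spleen, took 29.9% of reads in ON 2, 15.2% in MM 2 and 4.57% in ON 3, and at most 0.00362% in any other library. Saline library CT 4 had 6.62% of reads on mitochondrial genes, against at most 1.81% in the other saline libraries.

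**Figure D1:**
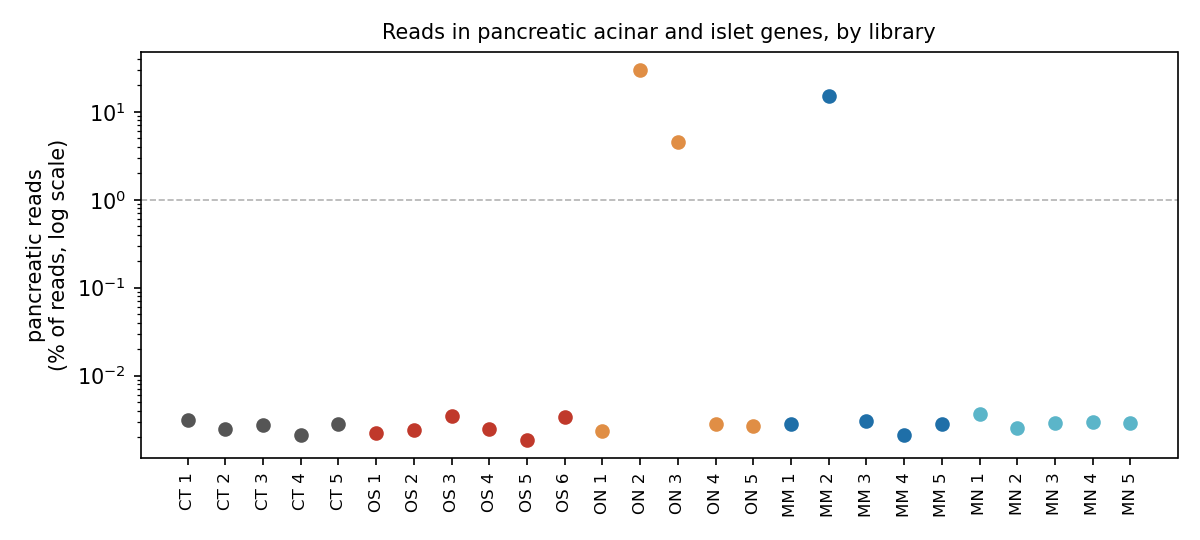
Reads in pancreatic genes as a percent of recovered reads (log scale) in each of the 26 libraries, coloured by code, with a dashed line at 1%. ON 2, MM 2 and ON 3 lie above the line at 29.9%, 15.2% and 4.57%.

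OVA against saline asked what the allergen changed in the spleen. Under OVA, 4 of 14 glucocorticoid response genes and 2 of 24 immediate early and heat-shock genes rose, while 18 of 89 ribosomal protein genes and 3 of 29 mitochondrially encoded genes fell. Both of these last lists were drawn up beforehand as signs of RNA quality. Errfi1, a feedback inhibitor of the EGF receptor (ENSMUSG00000028967, chromosome 4, 150938376 to 150953349), rose from 27.8 ± 8.58 FPKM under saline (n = 5) to 86.2 ± 45.8 under OVA (n = 11), a log2 difference of 1.39 ± 0.27 (limma adjusted p = 0.00705). All 11 OVA libraries were above the saline mean and 8 above the highest saline library, while ON 3, ON 4 and ON 5 lay within the saline range. Snrpf, a core protein of the spliceosome (ENSMUSG00000020018, chromosome 10, 93418891 to 93425568), fell from 42.2 ± 10.5 to 15.0 ± 4.46 FPKM, a log2 difference of -1.46 ± 0.27 (adjusted p = 0.00499), and all 11 OVA libraries lay below the lowest saline library. The calls of Snrpf, Gzma, Rpl32 and Lrrc32 held in every alternative run, leaving out each library included, while that of Errfi1 ended in a fit to only the OVA and saline libraries and with a single mean per treatment.

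In all, 340 of 15672 genes passed, 123 higher and 217 lower under OVA, of which 205 were protein-coding and 95 of the lower ones were pseudogenes. A 2-fold difference was reached by 19 of the higher and 71 of the lower genes. At an unadjusted p under 0.05 there were 2553 genes, against 784 that chance gives, and voom called 287. The other named rises were Adamts1, Gpr171, Hdc, Mir5125, Snord7, Bvht, Per1 and Rhob, with log2 differences of 1.02 to 1.28. Mir5125 and Snord7 are entries for small RNAs in poly(A)-selected libraries. Whether their reads came from these RNAs or from overlapping transcripts was not tested. Hdc, the enzyme that makes histamine, rose by 1.24 ± 0.28 (adjusted p = 0.0189), a call that ended without CT 3, without CT 4 and without the libraries with pancreatic reads. The other named falls were Rpl38, Tomm7, Rps29, mt-Nd3, Rpl35a, mt-Atp8, Ndufs6, Pet100 and mt-Co2, with log2 differences of -1.46 to -1.09. The count was 152 without CT 1, 218 without CT 2, 170 without CT 3, 178 without CT 5, 225 without ON 1 and 215 without ON 2, and 108 without the 3 libraries with pancreatic reads. A fit to only the OVA and saline libraries called 117, a single mean per treatment 87, no filter on low values 150 and library weights 1435.

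Of 14 glucocorticoid response genes, 4 rose and 10 did not pass, and 7 were higher when adjusted over the list alone. The median log2 difference was 0.65 (camera adjusted p = 4.75e-07 at the preset correlation), but adjusted p = 0.397 with an estimated correlation. Besides Errfi1, Per1, a clock gene that glucocorticoids induce, rose by 1.02 ± 0.26, Pdk4, which restrains glucose oxidation, by 0.92 ± 0.19, and Klf9, a glucocorticoid-induced transcription factor, by 0.56 ± 0.14. The calls of Per1 and Klf9 ended when any CT library, OS 1, OS 2, ON 1 or ON 2 was left out, that of Klf9 also without ON 3, and both without the libraries with pancreatic reads. Those of Pdk4, Per1 and Klf9 ended with a single mean per treatment. Without CT 4 the list's median was 0.47, the lowest of these fits. The list mean was above every saline library in 5 of 6 OS, 3 of 5 ON, 5 of 5 MM and 2 of 5 MN libraries. Of 24 immediate early and heat-shock genes, 2 rose, Nr4a2 by 0.86 and Nr4a3 by 1.01, and 2 were higher when adjusted over the list alone. The list's median was 0.59 (adjusted p = 2.36e-04 preset and 0.704 with an estimated correlation), and 0.30 without CT 4 (adjusted p = 0.0297 preset). The list mean was above every saline library in 5 of 6 OS but 0 of 5 ON libraries, with averages of 1.44 in OS and -0.13 in ON log2 from the saline mean.

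Ribosomal protein genes held the most falls of the lists described here. Of 89 tested, 18 fell, none rose and 71 did not pass, while 47 were lower and 1 was higher when adjusted over the list alone. The median log2 difference was -0.48 (adjusted p = 2.44e-21 preset and 0.397 with an estimated correlation). Rpl32 fell from 987 ± 323 to 491 ± 74.4 FPKM (log2 difference -0.97 ± 0.16, adjusted p = 0.00191), and Rpl38 from 895 ± 294 to 367 ± 220 FPKM (log2 difference -1.46 ± 0.34, adjusted p = 0.0254). The call of Rpl38 ended without CT 1, CT 3 or CT 5, and without the libraries with pancreatic reads. The list mean lay below every saline library in all 5 ON libraries, at -0.76 to -0.50 log2 from the saline mean, but in 3 of 6 OS, 3 of 5 MM and 2 of 5 MN libraries. The other 3 OS libraries lay between -0.10 and 0.03. Of 24 nuclear-encoded oxidative phosphorylation genes, 3 fell, with 12 lower when adjusted over the list alone and a median of -0.26 (adjusted p = 7.12e-10 preset and 0.397 with an estimated correlation). Cox5b, a subunit of complex IV, fell by 1.08 on the log2 scale, a call that ended without the libraries with pancreatic reads. Of 29 mitochondrially encoded genes, 3 fell, and 4 were lower when adjusted over the list alone (median -0.22, adjusted p = 0.0254 preset and 0.704 with an estimated correlation). That median depended on CT 4, without which it was 0.12 (adjusted p = 0.432 preset). It was -0.48 without CT 3, -0.46 without CT 5, -0.13 without OS 2, -0.35 without ON 2 and -0.33 without ON 3, and the call also ended without CT 1, ON 4 or ON 5. The call of mt-Atp8 ended without CT 1, CT 4 or CT 5. Its FPKM was near the floor, at 0.900 to 5.12 under saline and 0 to 1.94 under OVA, with 0 in ON 3 and ON 4.

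Among lymphoid genes, Prdm1 and Irf4, transcription factors of plasma cell differentiation, each rose by 0.57 (adjusted p = 0.0089 and 0.0126), the 2 of 13 plasma cell genes that passed, also when adjusted over the list alone (median 0.10, adjusted p = 0.0170 preset and 0.397 with an estimated correlation). Both calls ended with a single mean per treatment, that of Irf4 also without CT 1, and that of the list without CT 1 or CT 4. Without CT 5 the list's median was 0.16. Within OVA, all 6 OS libraries lay above the highest ON library for Irf4, and 5 of 6 for Prdm1. The pooled rise of these 2 genes therefore does not describe both codes alike. Lrrc32, which presents latent TGF-beta on regulatory T cells, rose by 0.62 ± 0.12 (adjusted p = 0.00794). It was the single member of 13 regulatory T-cell and co-inhibition genes to pass, with 2 higher when adjusted over the list alone (median 0.12, adjusted p = 0.00474 preset and 0.704 with an estimated correlation). That list's call ended without CT 4 (adjusted p = 0.170 preset), and its median was 0.22 without CT 1, 0.20 without CT 2, 0.19 without CT 3, 0.21 without CT 5 and 0.05 without OS 4. Of 15 cytotoxic and NK cell genes, Gzma, Ncr1 and Klrg1 fell, by log2 differences of -0.64, -0.80 and -0.48, and 3 were lower when adjusted over the list alone. That list was not called at the preset correlation (adjusted p = 0.121). Gzma, a granule protease, had 38.9 ± 6.09 FPKM under saline and 24.6 ± 3.10 under OVA (adjusted p = 0.00494), and all 11 OVA libraries lay below the lowest saline library. Of 9 type 2 response genes, limma called 0 (1 higher when adjusted over the list alone, median 0.09, adjusted p = 0.320 preset). In that list Stat6 differed by 0.05 ± 0.09 and Maf by 0.17 ± 0.11. All 13 megakaryocyte genes but 1 and all 18 neutrophil genes but 1 lay above 0, with medians of 0.32 and 0.54 (adjusted p = 0.00219 and 7.61e-04 preset, and 0.704 each with an estimated correlation). Over all genes 1 and 0 of them passed, and 1 and 1 were higher when adjusted over the list alone. The megakaryocyte call ended without CT 3 (median 0.22), and the neutrophil call without CT 4 (median 0.33), while the neutrophil median was 0.86 without CT 1.

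**Figure D2:**
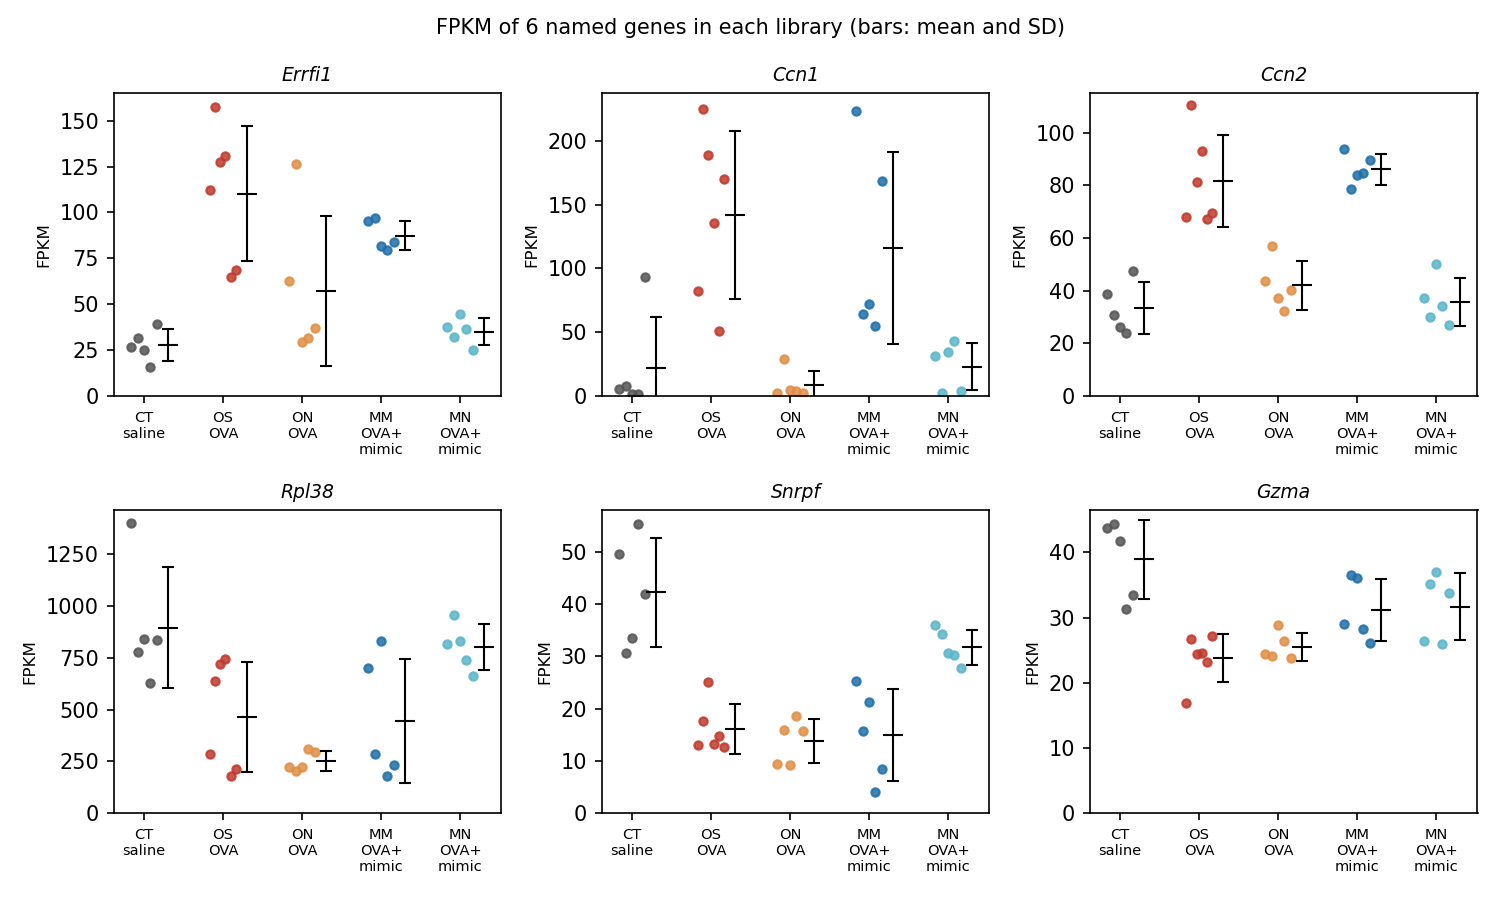
FPKM of Errfi1, Ccn1, Ccn2, Rpl38, Snrpf and Gzma in each library by code (points), with mean and SD (bars, which stop at 0 for Ccn1 in CT and ON, where the SD exceeds the mean). Errfi1 averaged 27.8 FPKM in CT and 110 in OS, and Gzma 38.9 in CT and 23.8 in OS.

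OVA with mimic against OVA asked what the mimic changed in allergen-treated mice. No single gene passed, and the smallest adjusted p was 0.137. The genes with the smallest p included Thbs1, which encodes an adhesive glycoprotein of platelets and matrix, with a log2 difference of -0.71 ± 0.14. It had 44.0 ± 9.92 FPKM under OVA (n = 11) and 27.1 with the mimic (n = 10), and 9 of 10 mimic libraries were below the OVA mean. The others were Tgfb1i1 at -0.51 ± 0.10, Gpcpd1 at -0.50 ± 0.10, Rps13-ps1 at 0.57 ± 0.11 and Rpl36a-ps1 at 0.96 ± 0.19. With limma, 0 of 15672 genes passed, 1590 had an unadjusted p under 0.05, and voom called 0. Library weights called 36, and leaving out OS 5 called 2.

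As groups, markers of neutrophils and of megakaryocytes were called lower with the mimic at the preset correlation, but not with an estimated one. All 18 neutrophil genes lay below 0, with a median of -0.78 (adjusted p = 1.26e-10 preset and 0.581 with an estimated correlation), and 8 were lower when adjusted over the list alone. S100a8 and S100a9, calcium-binding proteins of neutrophils, differed by -0.68 ± 0.36 and -0.71 ± 0.36 and did not pass. The list mean lay below every saline library in 3 of 5 MM and 1 of 5 MN libraries. It was above every saline library in MN 4, at 1.53 log2 from the saline mean, and MM 2 was at 0.89. All 13 megakaryocyte genes lay below 0, with a median of -0.43 (adjusted p = 1.93e-10 preset and 0.581 with an estimated correlation), and 9 were lower when adjusted over the list alone. Ppbp, a platelet chemokine, differed by -0.51 ± 0.18 and did not pass. Immunoglobulin light-chain V segments had a median of 0.30 over 99 genes (adjusted p = 9.71e-12 preset and 0.581 with an estimated correlation), and 0 passed when adjusted over the list alone. The 89 ribosomal protein genes had a median of 0.24 (adjusted p = 4.60e-11 preset and 0.802 with an estimated correlation), again with 0 when adjusted over the list alone. In the 15 cytotoxic and NK cell genes the median was 0.17 (adjusted p = 2.98e-05 preset and 0.581 with an estimated correlation), with 2 higher when adjusted over the list alone. The preset calls of these 5 lists held without each library in turn, each median within 1.5 times. Of these, only the megakaryocyte list was called at the preset correlation for MM and MN against both OS and ON. The neutrophil list was called for MM, with medians of -1.31 against OS and -1.21 against ON, but not for MN. Its pooled value therefore does not describe both codes alike, with list means of -0.61 in MM and 0.28 in MN. Light-chain segments were not called for MM against ON, ribosomal protein genes for MM against OS, or cytotoxic genes for MN against OS.

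OVA with mimic against saline asked what remained different from saline in mice that also received the mimic. No single gene passed here either. The smallest adjusted p was 0.172, for the predicted gene Gm10163 at -0.76 ± 0.14, followed by Gm14541, Gm37637, Gm12174 and Gm10036 at 0.247 each. With limma, 0 of 15672 genes passed, 1053 had an unadjusted p under 0.05, and voom called 0. Library weights called 36, and leaving out MN 2 called 1. All 14 glucocorticoid response genes lay above 0, with a median of 0.44 (adjusted p = 1.49e-07 preset and 0.390 with an estimated correlation), and 6 were higher when adjusted over the list alone. Without CT 4, whose list mean was -0.79 log2 from the saline mean, the median was 0.31. All 28 proliferation genes lay below 0, with a median of -0.31 (adjusted p = 4.36e-08 preset and 0.550 with an estimated correlation) and 0 passing when adjusted over the list alone. Without CT 4 it was -0.13 (adjusted p = 0.0302 preset). Of 23 erythroid genes 22 lay below 0, with a median of -0.40 (adjusted p = 8.69e-06 preset and 0.604 with an estimated correlation) and 0 passing when adjusted over the list alone. That call ended without CT 4 (median -0.16, adjusted p = 0.0549 preset). The lists for RNA quality also differed from saline in each code. Ribosomal protein genes had medians of -0.33 in MM and -0.16 in MN, and each preset call ended in 0 of 10 fits without a library. Mitochondrially encoded genes had medians of -0.34 in MM and -0.46 in MN, which were 0.04 and -0.05 without CT 4. None of these calls held with an estimated correlation.

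**Figure D3:**
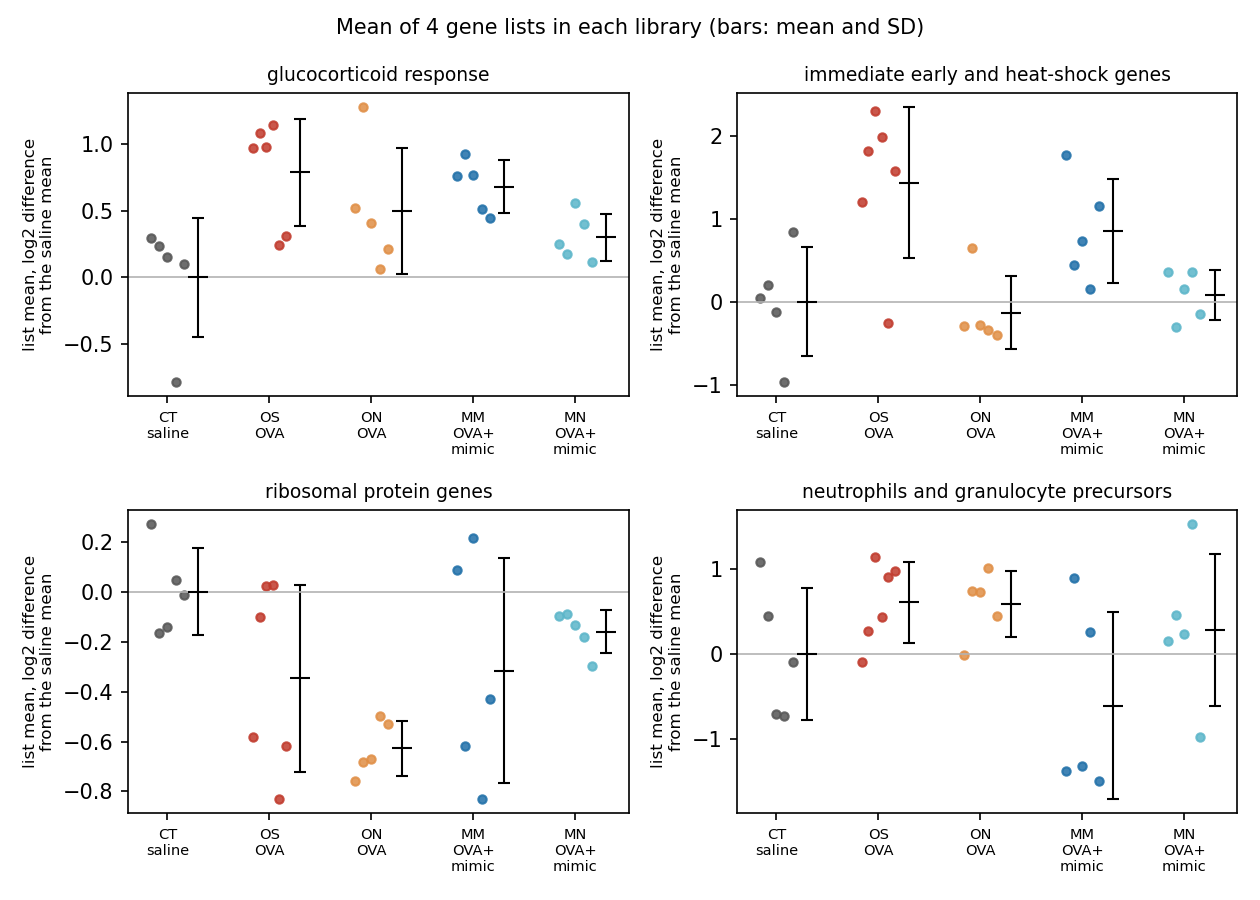
Mean log2 difference from the saline mean over the genes of 4 lists in each library, by code (points), with mean and SD (bars). Immediate early genes averaged 1.44 in OS and -0.13 in ON, and the ribosomal protein mean lies below every saline library in 3 of 6 OS and 3 of 5 MM libraries.

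OS against ON compared the 2 codes that share OVA as their stated treatment. Of 24 immediate early and heat-shock genes 3 rose in OS, while neither that list nor the inflammatory list held with an estimated correlation (adjusted p = 0.230 each). Ccn1, an early-response matrix protein (ENSMUSG00000028195, chromosome 3, 145352731 to 145355736), had 142 ± 65.9 FPKM in OS (n = 6) and 8.59 ± 11.4 in ON (n = 5), a log2 difference of 4.31 ± 0.81 (limma adjusted p = 0.0289). Adm, which encodes the vasodilator peptide adrenomedullin, had 6.93 ± 2.65 and 1.98 ± 0.718 FPKM (log2 difference 1.37 ± 0.20, adjusted p = 0.00217). Ctla4, an inhibitory receptor of T cells, rose by 1.83 ± 0.38 (adjusted p = 0.0417), and all 6 OS libraries were above the ON mean for each of these genes. The calls of Ccn1 and Ctla4 ended without OS 2, OS 3, OS 4, ON 1, ON 3, ON 4 or ON 5, while that of Adm held without each library in turn and ended in a fit to OS and ON alone.

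In all, 29 genes passed, 27 higher and 2 lower in OS, with 1658 at an unadjusted p under 0.05 and 40 called by voom. Atf3, Fosb, Dusp1, Gem, Adamts1 and Dusp5 were also higher, by 1.65 to 2.66, and Exoc8 and Slc35c1 were lower, by -0.50 and -0.47. Of the immediate early and heat-shock genes 17 were higher when adjusted over the list alone, with a median of 1.33 (adjusted p = 8.88e-23 preset and 0.230 with an estimated correlation). Of 19 inflammatory cytokines and chemokines 0 passed over all genes and 13 were higher when adjusted over the list alone (median 0.75, adjusted p = 1.40e-12 preset and 0.230 with an estimated correlation). Both preset calls held without each library in turn, but OS 5, with list means of -0.26 and -0.26 log2 from the saline mean, lay within the range of the ON libraries. Ribosomal protein genes, listed as a sign of RNA quality, were also called higher at the preset correlation, with a median of 0.27. That call ended in 0 of 11 fits without a library. Nuclear-encoded oxidative phosphorylation genes had a median of 0.16, or 0.08 without OS 3, and their preset call ended in 3 of 11 fits. Neither list was called with an estimated correlation. The 4 pancreatic genes tested had a median of -4.10 (adjusted p = 0.00273 preset and 0.619 with an estimated correlation), which was -2.24 without ON 2 (the call ended) and 0.09 without the 3 libraries with pancreatic reads. The count of 29 was 3 without OS 2, OS 3, ON 3, ON 4 or ON 5, 4 without ON 1, 5 without OS 4, 47 without OS 1, 216 without ON 2 and 260 without OS 5. A fit to OS and ON alone called 0, with limma, a pseudocount of 0.1 gave 17, no filter 6, library weights 564, scaling to total reads 68 and removal of a gene-length trend 47, and one without the 3 libraries with pancreatic reads called 123.

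MM against MN made the same comparison between the 2 codes of mice given OVA with the mimic. Ccn2, a matrix protein related to Ccn1 (ENSMUSG00000019997, chromosome 10, 24471340 to 24474581), had 86.2 ± 5.82 FPKM in MM and 35.8 ± 8.95 in MN (n = 5 each), a log2 difference of 1.27 ± 0.19 (limma adjusted p = 0.00611). Bmp2, a growth factor, rose by 0.71 (adjusted p = 0.0353), Tcf7l2, a transcription factor of the Wnt pathway, by 0.47 and Ranbp9 by 0.45. All 5 MM libraries lay above the highest MN library for these 4 genes. The call of Ccn2 held in every alternative run, while those of Bmp2, Tcf7l2 and Ranbp9 ended under scaling to total reads and without MM 1, MM 4, MM 5, MN 1, MN 2, MN 3 or MN 5. In all, 27 genes passed, 9 higher and 18 lower in MM, and none of the lower genes could be named under the rule. Of the 18 lower genes 13 were pseudogenes, 4 of them of ribosomal proteins. There were 1137 at an unadjusted p under 0.05, and voom called 20. Neutrophil genes had a median of -0.95 (adjusted p = 2.07e-08 preset and 0.845 with an estimated correlation), with all 18 below 0 and 0 passing when adjusted over the list alone. Immediate early genes had a median of 0.95 (adjusted p = 6.86e-08 preset and 0.845 with an estimated correlation), with 3 of 24 higher when adjusted over the list alone. Both calls held without each library in turn. Ribosomal protein genes, listed as a sign of RNA quality, had a median of -0.11, which was 0.0098 without MM 4. Their preset call ended in 2 of 10 fits without a library. The count of 27 was 1 without MM 4, MM 5 or MN 1, 2 without MN 2 or MN 3, 8 without MN 5, 15 without MM 1 and 16 without MN 4. It was 123 in a fit to MM and MN alone, 7 with no filter and 474 with library weights.

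**Figure D4:**
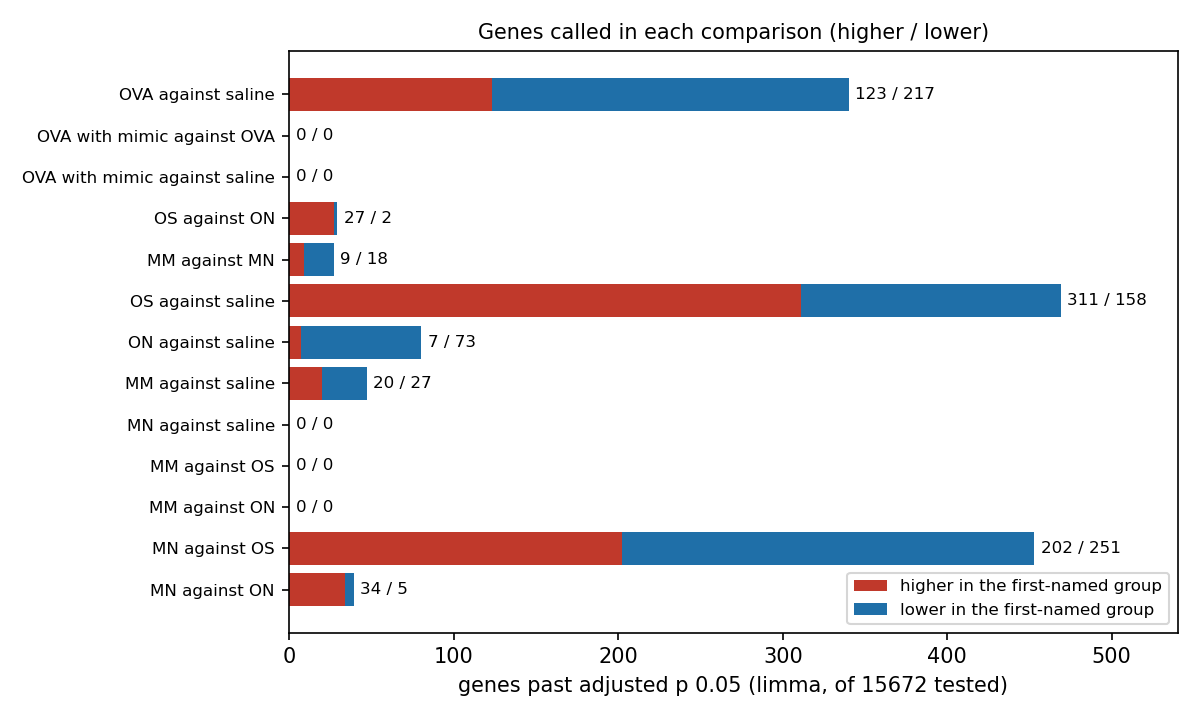
Genes past an adjusted p of 0.05 (limma, of 15672 tested) in each of the 13 comparisons, higher and lower in the first-named group. MN against saline has 0 and OS against saline 469.

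Each code was also set against saline. In OS, 469 genes passed, 311 higher and 158 lower, and in ON 80, 7 higher and 73 lower. In MM 47 passed, 20 higher and 27 lower, and in MN limma called 0, with 451 at an unadjusted p under 0.05 and 0 by voom. Errfi1 differed from saline by 1.93 in OS, 0.84 in ON, 1.67 in MM and 0.36 in MN, and Snrpf by -1.35, -1.57, -1.63 and -0.37. Of 24 immediate early genes 10 rose in OS, with 17 higher when adjusted over the list alone (median 1.34, or 0.87 without CT 4, adjusted p = 1.35e-13 preset and 0.445 with an estimated correlation). In ON their median was -0.08 and the list was not called (adjusted p = 0.425 preset). Of 15 circadian clock genes, 2 were higher in MM when adjusted over the list alone, with a median of 0.28 (adjusted p = 7.88e-06 preset and 0.0355 with an estimated correlation), the single list call in the 13 comparisons that held with an estimated correlation. That held in 3 of 10 fits without a library of MM or saline, and the median was 0.16 without CT 4. The OS count was 274 without CT 2, 261 without CT 3, 285 without OS 2 and 262 without OS 4. In ON it was 30 without CT 1, 50 without CT 3, 38 without CT 5, 36 without ON 1, 37 without ON 2, 27 without ON 3 and 13 without the 3 libraries with pancreatic reads. In MM it was 22 without MM 4 and 20 without MM 5. A fit to only the groups compared gave 88, 49 and 17 for OS, ON and MM, library weights 1353, 859 and 518, and no filter 283 for OS and 33 for ON, while an FPKM of at least 5 gave 149 for ON. Of 100 splits for OS against saline, the real one included, 5 gave as many genes.

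Between the codes of the 2 OVA treatments, MN differed from OS in 453 genes, 202 higher and 251 lower, and from ON in 39, 34 higher and 5 lower. MM against OS and MM against ON gave 0 with limma and 0 with voom, with 905 and 566 genes at an unadjusted p under 0.05. MN against OS gave 281 without OS 2, 288 without OS 3, 274 without OS 4, 245 without MN 1, 189 without MN 2, 203 without MN 3, 248 without MN 4 and 233 without MN 5. MN against ON gave 16 without ON 1, 23 without ON 2, 7 without ON 3, 20 without MN 1 or MN 4, 9 without MN 2, 14 without MN 3, 22 without MN 5 and 0 without the 3 libraries with pancreatic reads. MM against OS gave 10 without OS 5 and 2 without OS 6, and MM against ON gave 4 without ON 2 and 1 without MM 5. MN against OS gave 246 with no filter, 249 with scaling to total reads and 1746 with library weights, and MN against ON 23 with no filter or a pseudocount of 0.1, 632 in a fit to the 2 codes alone and 755 with library weights. Library weights gave 1 for MM against OS and 16 for MM against ON.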

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

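The tests of ribosomal protein pseudogenes and of an OVA effect on pancreatic reads, the values with a gene-length trend removed or pancreatic libraries left out, and the numbers of libraries within the saline range, were chosen only after the results were seen. Of 465 group values tested for a library far from the others, 49 stood out. The cut-off gives about 1 in 20, or 23.25, if values are independent and normally spread. FPKM of genes within a library are not independent, so the excess over that number is not a test. ON 2 held 19 of the 49 and CT 4 held 14.

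In ON 2, pancreatic genes took 29.9% of reads and the 10 largest genes 24.6%. Its FPKM stood apart from the other ON libraries for Ctrb1 at 78387, Cela1 at 12902, Prg2 at 778, Herpud1 at 228, Dusp1 at 115, mt-Co2 at 52.7, Ccn1 at 28.8, Dusp5 at 25.9, Gem at 16.4, Slc35c1 at 10.2, Atf3 at 8.84, Hdc at 8.57, Nr4a3 at 6.99, Nr4a2 at 3.34, Fosb at 3.08 and Ncr1 at 2.39. Its mean for immediate early genes was 0.65 log2 above saline. In MM 2, pancreatic genes took 15.2% of reads and the 10 largest genes 12.5%, with Ctrb1 at 35787 and Cela1 at 5698 FPKM.

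CT 4 stood apart from the other saline libraries in mitochondrial reads at 6.62%, reads on the 10 largest genes at 11.8%, genes above 0 at 20681, and effective over total reads at 0.802. Its glucocorticoid and inflammatory list means were -0.79 and -0.96 log2 from the saline mean. Its FPKM stood apart for Rpl32 at 1561, Mki67 at 690, Hsp90aa1 at 288, mt-Co2 at 184, Gm12174 at 48.1, Ndufa9 at 38.9, mt-Nd3 at 22.5 and Per1 at 8.13.

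In other libraries, the FPKM that stood apart were Rpl38 at 1398 in CT 1, Ccn1 at 93.3, Fosb at 1.69 and Nr4a2 at 1.41 in CT 5, Snord7 at 27.3 in OS 4, Edem1 at 49.2 in OS 5, Stat6 at 47.5 in ON 1, Ctrb1 at 3.30 in MN 1 and Herpud1 at 55.9 in MN 5. The inflammatory list mean was 0.90 in MM 1 and -0.43 in MN 2, and MN 2 had 14.7 M reads. Libraries with the same stated treatment differed in 29 genes between OS and ON and in 27 between MM and MN, by the test of each difference.

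Ribosomal protein genes had a median log2 difference of -0.48 under OVA. Removing a trend with gene length left -0.44, which argues against that trend as the whole cause. Reads shifted to pseudogenes would raise these, but the median of 110 ribosomal protein pseudogenes was -0.46 ± 0.07 (bootstrap SE). Without CT 4 the median was -0.44, so that library alone does not account for it. An effect of OVA and a difference in RNA quality, handling or batch stay open, since the labels give no batch and 3 of 6 OS libraries lay within the saline range.

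Immediate early genes had a median of 1.33 in OS against ON. Without ON 2 and ON 3 it was 1.62, which argues against the pancreatic libraries as the cause. In 5 of 6 OS libraries the list mean was above the highest ON library, so most but not all OS libraries carried the difference. That is more than was set beforehand for a few libraries, and less than the full 6 set for the whole code. The test therefore does not decide between them. The labels define neither the codes nor the handling of the organs. What the codes stand for stays open and untested.

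Pancreatic reads in ON 2, ON 3 and MM 2 are consistent with pancreas tissue taken along with the spleen. Over 22 pancreatic genes with at least 100 reads in both, the log2 ratio of ON 2 to MM 2 had an SD of 0.379 around a mean of 1.16, so the genes kept nearly a single ratio. The abundant Ctrb1 had 78387 and 35787 FPKM, and of 25 genes in the list 4 reached an FPKM of 1 in at least 5 libraries. The other 18 libraries from mice given OVA held 0.00187% to 0.00362% (median 0.00280%), and saline libraries 0.00212% to 0.00316%. These 18 showed no shared rise under OVA. The values by library had already shown this, so it adds no independent test.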

How the results depend on the processing

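Voom, scaling to total reads, removal of a gene-length trend and leaving out the 3 libraries with pancreatic reads were chosen after the data were seen. The counts under voom and median-ratio scaling stayed within 1.5 times in all 13 comparisons. In other settings counts moved, some of them with fewer libraries or more genes in the fit, and the cause was not tested. A pseudocount of 0.1 gave 17 for OS against ON and 23 for MN against ON. With no filter on low values, which tests more genes, OVA against saline gave 150, OS against ON 6, MM against MN 7, OS against saline 283, ON against saline 33, MN against OS 246 and MN against ON 23. An FPKM of at least 5 gave 149 for ON against saline. A fit to only the groups compared gave 117 for OVA against saline, 0 for OS against ON, 123 for MM against MN, 88 for OS against saline, 49 for ON against saline, 17 for MM against saline and 632 for MN against ON. With replicate numbers as a block, although they do not pair the libraries, OVA against saline gave 184, OS against ON 3, OS against saline 306, ON against saline 40, MN against OS 258 and MN against ON 19. A single mean per treatment gave 87 for OVA against saline. Library weights gave 1435 for OVA against saline, 36 each for OVA with mimic against OVA and against saline, 564 for OS against ON, 474 for MM against MN, 1353 for OS, 859 for ON and 518 for MM against saline, 1 for MM against OS, 16 for MM against ON, 1746 for MN against OS and 755 for MN against ON. Scaling to total reads gave 68 for OS against ON and 249 for MN against OS, and removal of the length trend 47 for OS against ON. Without the 3 libraries with pancreatic reads, OVA against saline gave 108, OS against ON 123, ON against saline 13, MM against ON 1 and MN against ON 0, the opposite movement weakened to r = -0.23, and the pancreatic list reversed to 0.0930 in OS against ON. For the seed test, the call ended with an 8-base site (difference 0.0023, permutation p = 0.0780) and with no filter (-0.0034, permutation p = 0.106), with site genes above the matched sets in each. It held with a pseudocount of 0.1 (permutation p = 0.0384), an FPKM of at least 5 (0.00660) and median-ratio scaling (0.0284).

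Leaving out each library in turn gave 152 to 484 genes for OVA against saline, 0 to 2 for OVA with mimic against OVA, 0 to 1 for OVA with mimic against saline, 3 to 260 for OS against ON, 1 to 26 for MM against MN, 261 to 633 for OS against saline, 27 to 103 for ON against saline, 20 to 70 for MM against saline, 0 to 0 for MN against saline, 0 to 10 for MM against OS, 0 to 4 for MM against ON, 189 to 660 for MN against OS, 7 to 34 for MN against ON, and r of -0.51 (without CT 4) to -0.21 (without ON 2). Libraries that moved a count by over 1.5 times are named with their values beside each comparison. Over all named genes these fits gave 795 results on the same side of the threshold, 265 calls lost, 2 gained and 0 reversed. Of 68 list calls in the 3 treatment comparisons, OS against ON and MM against MN, 68 were lost with an estimated correlation. Leaving out each library for these lists, also chosen after the data were seen, gave 893 results on the same side of the threshold, 120 calls lost and 2 reversed, with means of 0.13 for mitochondrial genes in OVA against saline without CT 4 (-0.40 without CT 2) and -0.0511 for heavy-chain V segments in OVA with mimic against saline without CT 1 (0.28 without CT 2). Depth limits low values, since 1 read on 1 kilobase is an FPKM of 0.0520 to 0.0899.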

Other observations

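The opposite movement by code, and the lists without each library, were chosen only after the results were seen. Replication-dependent histone genes, whose transcripts mostly lack poly(A) tails, had a median of 0.59 over 28 genes in OS against ON (adjusted p = 3.06e-07 preset and 0.619 with an estimated correlation), with 2 higher when adjusted over the list alone, and the preset call held without each library in turn. Immunoglobulin heavy-chain V segments had medians of -0.40 in OS against ON (adjusted p = 3.06e-07 preset and 0.849 with an estimated correlation) and -0.46 in MM against MN (adjusted p = 7.07e-11 preset and 0.845 with an estimated correlation). In OS against ON that median was -0.19 without OS 4 and -0.61 without OS 5. Adipocyte markers, from tissue that can adjoin the spleen, had a median of -0.63 over 8 genes in OVA against saline (adjusted p = 0.0254 preset and 0.704 with an estimated correlation), with 0 passing when adjusted over the list alone, a call that ended without CT 1 (median -0.37), CT 2 (-0.40), CT 4 or ON 5.

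Whether the mimic moves genes back towards saline was tested as a hypothesis. With no library shared between the 2 effects, r across 15672 genes was -0.36, and 2 of 100 relabellings were as low (permutation p = 0.0297, one-sided). Genes are not independent replicates. A partial return of expression towards saline would give such an r. So would a batch or handling shared by saline and MN libraries, and the labels do not let these be told apart. Against saline, limma called 0 genes in MN and 47 in MM, although both share 1 stated treatment. Also, r was -0.21 without ON 2 and -0.23 without the 3 libraries with pancreatic reads, each at permutation p = 0.0792. By code, r was -0.45 for OS with MN, -0.42 for ON with MN, -0.13 for OS with MM and -0.16 for ON with MM, with 1, 0, 27 and 23 of 100 relabellings as low. Whether MM and MN differ in r was not tested.

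Whether the mimic lowers transcripts with a match to its seed was tested over 11901 genes with a 3′ UTR, 398 of them with a site. The median log2 difference of site genes minus genes without a site was -0.0059, against -0.0211 in random sets matched to the site genes (95% from -0.0341 to -0.0077). Site genes lay higher than the matched sets (permutation p = 0.0314, two-sided, and 0.984, one-sided for lower values), so no lowering of the site genes as a set was found. That p comes from draws of genes and leaves out the spread between libraries, so it decides neither a rise nor a lowering. Site genes lay higher in all 6 settings, but not past 0.05 with an 8-base site, in 84 genes (0.0023 against -0.0258, permutation p = 0.0780), or with no filter on low values (permutation p = 0.106). Across libraries a related contrast was taken, the mean log2 of site genes minus that of all genes without a site. It differed by -0.0084 between 10 mimic and 11 OVA libraries (permutation p = 0.663, two-sided), with SDs of 0.0321 and 0.0519. It used means and no matched sets, so it is no check on the comparison with those sets. The precursor gene Mir676 was listed at 0 in all libraries. Poly(A)-selected libraries are not made to capture such small RNAs, so this does not show whether the mimic reached the spleen.

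For each comparison, the real split and others drawn from the same libraries, with groups of the same sizes, made up 100 splits. With the real split included, 3 gave as many genes as OVA against saline (340, highest other 3547) and 2 as many as MM against saline (47, highest other 109). Only 1, the real split, gave as many for OS against ON (29, highest other 14), MM against MN (27, highest other 1) and ON against saline (80, highest other 1). The same held for MN against OS (453, highest other 27) and MN against ON (39, highest other 2). Such counts were rare among the drawn splits for these 7. With 100 splits each and no correction over the 13 comparisons, this does not exclude chance. For OS against saline 5 splits gave as many (469, highest other 1990), and chance cannot be excluded there either. Every split reaches a count of 0, so 100 of 100 decide nothing for the 5 comparisons with none, with highest others of 1 for OVA with mimic against OVA, 4 for OVA with mimic against saline, 1 for MN against saline, 3680 for MM against OS and 1 for MM against ON. Splits that called 3547 and 1990 genes, several times the real 340 and 469, and 3680 where the real split called 0, point to a structure of the samples other than the groups compared.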
